A study of Mus musculus with 32 samples.

How the data were processed

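Livers came from male C57BL/6 mice aged 8 weeks, adrenalectomized and injected with a water-soluble complex of dexamethasone (1 mg/kg in 300 ul) or with vehicle, and were taken 1 h later, per the labels and the series' design text. The chromatin was examined by DNase-seq, which marks accessible sites by their sensitivity to DNase I, and by ChIP-seq for GR, C/EBPβ and RNA polymerase II. Per the submitters' processing notes, CASAVA 1.8 and the genome build mm9 were used. The aligner, the peak caller and its threshold are not given in the sources used here, nor is whether the lists were called on single or pooled samples.

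The deposited files used here are 5 interval lists, and the authors' values in them are positions only: a chromosome, a start, an end and a running identifier. They hold no count, score or other signal, and 0 columns of per-sample values were left unused. The labels do not state whether positions count from 0 or 1, so intervals were treated as half-open and positions are printed as in the files. All 11666 GR intervals were 150 bp wide. The C/EBPβ lists were drawn from 1 merged set of 27793 identifiers: the 20313 peaks in both lists had the same coordinates in both, and the 5079 and 2401 peaks in 1 list only were all 150 bp wide. Sharing of C/EBPβ peaks was thus set by the deposited merge. DHS had median widths of 591 bp (dexamethasone) and 596 bp (vehicle). In the dexamethasone DHS list, 1160 intervals were exactly 150 bp and 692 exactly 251 bp wide, and 3 rows were duplicates. In that list 1 number of the running identifiers was not present. The adenovirus, polymerase II and input samples, and GR ChIP-seq as separate treatments, were not analysed here.

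Regions were called shared when they overlapped by at least 1 bp. Shares have 95% Wilson intervals and a jackknife standard error obtained by leaving out each chromosome in turn. Expected shares came from 1000 random placements (seed 7) of each GR interval on the span of its own chromosome covered by the lists. These placements take no account of unmappable sequence, so an alternative placed each peak within a window of 1 Mb around it. Odds ratios have 95% Woolf intervals and two-sided Fisher's exact tests, or Mantel-Haenszel estimates over 10 strata (deciles) of DHS width. P-values under 1e-300 are given as below it, and 16 odds ratios were adjusted together by the Benjamini-Hochberg method. Positions in a dexamethasone DHS outside vehicle DHS were split, after seeing the data, into dex-only DHS and parts of shared DHS beyond the vehicle interval, and the 8 odds ratios of this split were adjusted as a family of their own. Regions on one chromosome are not independent, and the p-values compare classes of regions, not treatments. The width of DHS was compared between lists where a dexamethasone and a vehicle DHS overlapped each other and no other, with a permutation test of the difference in medians (100000 permutations).

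The design, the alternatives and the rule for named regions were fixed before the data were examined. The rule named the 5 windows of 100 kb with most GR peaks, the 5 with most dex-only DHS, and the highest-scored GR peaks, DHS and C/EBPβ peaks, with the widest in their place where no score exists. GR peaks and list-specific C/EBPβ peaks all had the same width, so none was named singly, and DHS were named by width. Planned comparisons of the score or width of GR peaks by class, of signal per region and of motif content were not run, since the lists hold positions only and no mm9 sequence was used here. Fixed gene lists were not used, since the gene table at hand refers to GRCm38.p6 and positions were not converted between builds. In place of signal, DHS width was compared.

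Alternatives changed the overlap rule (the larger part of the shorter interval, the centre, or within 500 bp), the DHS used (those above the median width, or lists of the same length by width), the interval width (300 bp), the chromosomes (autosomes), the strata and the C/EBPβ list. After seeing the data, an alternative without 150-bp and 251-bp DHS, chromosome Y and 7 windows with over 22 DHS was added. The scripts were tested on simulated lists: planted shares of 20.0% and 80.0% of GR peaks in vehicle DHS came back as planted, and planted odds ratios of 1 and 4 over 56794 DHS came back as 1.00 and 4.00 with width strata, against 2.10 and 6.95 without. The planted peaks lay at DHS centres or away from any DHS, so the shares tested the counting only. Of 100 simulated lists with no association, 8 were called at p of 0.05 or under. These lists had 2334 peaks, fewer placements and a one-sided p, so they do not calibrate the two-sided p reported here. Overlap counts of GR peaks with the other 4 lists equalled those of bedtools 2.31.1. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.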

Results

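The series examined the liver of adrenalectomized male mice injected with dexamethasone, a synthetic ligand of the glucocorticoid receptor (GR), or with vehicle, and its title asks whether C/EBP keeps chromatin accessible and assists GR recruitment. Adrenalectomy removes the main source of the animals' own glucocorticoid, so vehicle livers stand for a state of low hormone. C/EBPβ is a leucine zipper transcription factor of hepatocytes. The 32 samples fall into 16 groups: DNase-seq, GR ChIP-seq, C/EBPβ ChIP-seq, RNA polymerase II ChIP-seq and input from dexamethasone and vehicle livers (2 samples in each of these 10 groups), and DNase-seq, GR and C/EBPβ samples from dexamethasone-treated livers given an adenovirus with GFP or with a dominant-negative C/EBP. The deposited lists used here are 5 sets of mm9 intervals: 11666 GR peaks, 25392 C/EBPβ peaks after dexamethasone, 22714 C/EBPβ peaks after vehicle, 63473 DNase I hypersensitive sites (DHS) after dexamethasone and 56794 DHS after vehicle. The adenovirus, polymerase and input samples were not analysed here. The GR list carries no treatment in its name and was used as the series' set of GR peaks. Each condition has 1 list per assay, with no height, count or replicate column. Read depth is therefore unknown, differences between conditions have no replicate check, and p-values compare classes of regions within these lists. Intervals in parentheses after shares are 95% Wilson intervals and cover counting error only.

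The first comparison asks whether GR peaks lie in chromatin that was accessible in vehicle livers. Most did. Of the 11666 GR peaks, 9236 (79.2%, 78.4 to 79.9) overlapped a DHS of the vehicle list by at least 1 bp. A further 2050 (17.6%, 16.9 to 18.3) lay outside vehicle DHS but overlapped a DHS of the dexamethasone list, and 380 (3.26%, 2.95 to 3.60) overlapped neither. Split after seeing the data, 1819 of the 2050 (15.6% of all GR peaks, 14.9 to 16.3) overlapped a dexamethasone DHS that shared no base with any vehicle DHS (dex-only DHS), and 231 (1.98%, 1.74 to 2.25) lay in a shared DHS beyond its vehicle interval. Random placement of the same intervals on their own chromosomes gave 1.84% in vehicle DHS and 0.529% in dexamethasone DHS outside them, so the observed shares were 42.9 and 33.2 times the random ones. These 3 shares (79.2%, 17.6% and 3.26%) differed from the random placements with p = 0.002 (two-sided, n = 11666 peaks), the smallest value that 1000 placements can give. Placement within 1 Mb gave the same p, but its expected shares are not given here. The ratios of 42.9 and 33.2 thus hold for whole-chromosome placement only. The jackknife standard error over chromosomes was 0.50 points for the vehicle DHS share and 0.431 points for the 17.6%. The share outside both DHS lists was 14.2% when only DHS above the median width of each list were used. It was 9.27% when all intervals were reduced to 300 bp around their centres. These settings drop DHS or trim most of them, so a higher share was largely built in.

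Many GR peaks also coincided with C/EBPβ peaks found without hormone. A C/EBPβ peak of the vehicle list overlapped 5885 GR peaks (50.4%, 49.5 to 51.4), and a C/EBPβ peak of the dexamethasone list overlapped 7238 (62.0%, 61.2 to 62.9). Random placement gave 0.286% and 0.320% (p = 0.002 for both, n = 11666 peaks, the smallest possible). In the vehicle state, 5713 GR peaks (49.0%) lay in a DHS and on a C/EBPβ peak, 3523 (30.2%) in a DHS without C/EBPβ, 172 (1.47%) on a C/EBPβ peak outside DHS, and 2258 (19.4%) had neither. The median distance from a GR centre to the nearest vehicle C/EBPβ centre was 137 bp (quartiles 18 and 6689 bp), against 8652 bp from the centres of vehicle DHS without GR and 89200 bp after random placement. For the dexamethasone C/EBPβ list the median was 45 bp (quartiles 14 and 2126 bp), against 7322 bp and 88595 bp. Where a GR and a dexamethasone C/EBPβ peak overlapped (7265 pairs), their centres were a median of 19 bp apart, and 53.0% of pairs had centres within 20 bp.

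C/EBPβ occupancy differed sharply between the accessibility classes of GR peaks. Among GR peaks in vehicle DHS, 5713 of 9236 (61.9%, 60.9 to 62.8) had a vehicle C/EBPβ peak. Among GR peaks in dexamethasone DHS outside vehicle DHS the number was 158 of 2050 (7.71%, 6.63 to 8.94), of which 144 were among the 1819 in dex-only DHS (7.92%, 6.76 to 9.25), and among those in neither DHS list 14 of 380 (3.68%, 2.21 to 6.09). The odds of a vehicle C/EBPβ peak were 21.3 times higher for GR peaks inside than outside vehicle DHS (18.1 to 25; Fisher's exact test, two-sided, p below 1e-300). A contrast of this kind was not limited to GR peaks, since 82.9% of all vehicle C/EBPβ peaks overlapped a vehicle DHS. Among dexamethasone DHS without a GR peak, 27.1% of shared and 6.26% of dex-only ones held a vehicle C/EBPβ peak. The direction at GR peaks held in each alternative tried. For GR peaks in a dexamethasone DHS, with 10 strata of its width added after seeing the data, the odds ratio was 22.4. It was 7.75 with the dexamethasone C/EBPβ list, 5.32 with DHS above the median width and 7.25 with 300-bp intervals. The latter settings drop or trim DHS, so some GR peaks in vehicle DHS counted as outside them.

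Gain of C/EBPβ between the lists was also unequal. A C/EBPβ peak found after dexamethasone and absent from the vehicle list (dex-only C/EBPβ) lay at 410 of the 2050 GR peaks in dexamethasone DHS outside vehicle DHS (20%, 18.3 to 21.8), and at 960 of the 9236 GR peaks in vehicle DHS (10.4%, 9.79 to 11). The odds ratio was 2.16 (1.90 to 2.45; Fisher p = 5.28e-30, adjusted p = 7.04e-30 by Benjamini-Hochberg over the 16 odds ratios of the same family). Many GR peaks in vehicle DHS held a vehicle C/EBPβ peak and so could not count as a gain. Among GR peaks with no vehicle C/EBPβ peak the order turned: 410 of 1892 (21.7%) in dexamethasone DHS outside vehicle DHS and 960 of 3523 (27.2%) in vehicle DHS had a dexamethasone C/EBPβ peak (odds ratio 0.739, 0.647 to 0.843; Fisher p = 6.00e-06, adjusted p = 6.40e-06). For the 1819 GR peaks in dex-only DHS alone, the odds ratios were 2.10 (1.84 to 2.40) and 0.721 (0.627 to 0.828). For the 231 in shared DHS they were 2.63 (1.93 to 3.59) and 0.884 (0.644 to 1.21), the latter not past the threshold (Fisher p = 0.479, adjusted p = 0.479 over the 8 odds ratios of the split). No C/EBPβ peak of either list was found at 27.8% of GR peaks in vehicle DHS, 72.5% in dex-only DHS, 70.6% in shared DHS beyond the vehicle interval and 91.1% in neither DHS list.

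**Figure D1:**
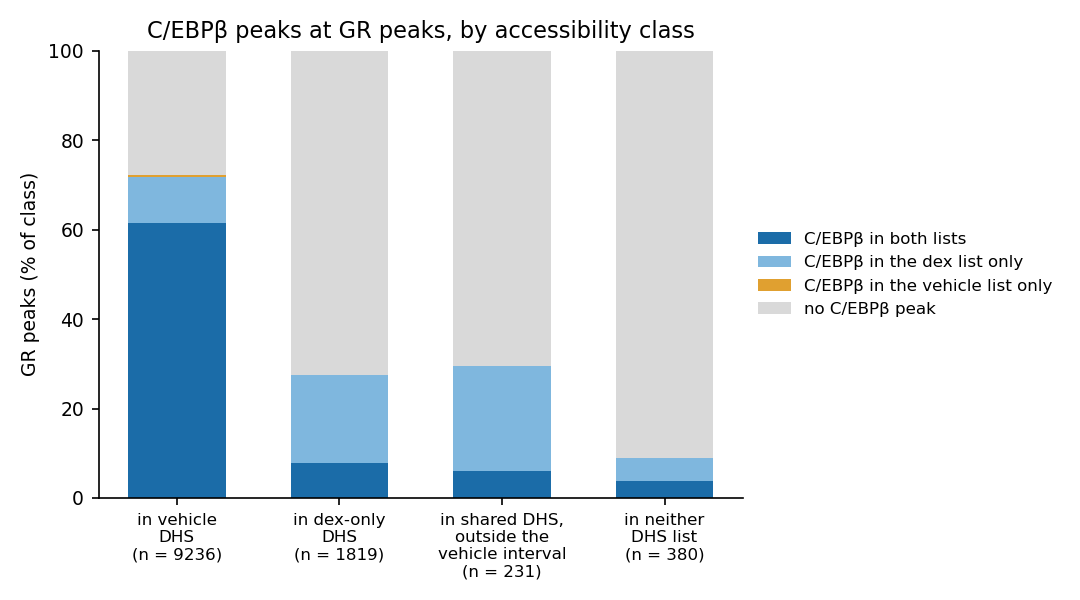
Stacked bars give the percent of GR peaks (y axis) with a C/EBPβ peak in both lists, in 1 list only or in neither list, for GR peaks in vehicle DHS, in dex-only DHS, in shared DHS beyond the vehicle interval and outside both DHS lists. Peaks with no C/EBPβ make up 27.8%, 72.5%, 70.6% and 91.1% of the 4 classes.

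The next comparison asks where accessibility differed between the dexamethasone and vehicle lists. Of the dexamethasone DHS, 15076 (23.8%, 23.4 to 24.1) were absent from the vehicle list, and of the vehicle DHS 8488 (14.9%, 14.7 to 15.2) were absent from the dexamethasone list. A GR peak lay in 1788 dex-only DHS (11.9%, 11.4 to 12.4) but in only 13 vehicle-only DHS (0.153%, 0.0895 to 0.262), an odds ratio of 87.7 (50.8 to 151; Fisher p below 1e-300). That ratio was chosen after seeing the data. A vehicle-only DHS shares no base with any dexamethasone DHS, while 11270 of the 11666 GR peaks overlapped a dexamethasone DHS. The low vehicle-only share was thus largely built in, and the ratio mostly restates that GR peaks lay in dexamethasone DHS. It was 3.67 with 300-bp intervals, 6.21 with DHS above the median width and 43.5 when a centre had to lie within the other interval. The settings of 3.67 and 6.21 trim or drop DHS, so DHS shared in the full lists could count as list-only. The vehicle-only share of DHS was 18.2% and 20.2% there. Within strata of DHS width, also added after seeing the data, the ratio was 64.3 (37.4 to 110). It was 96.2 with the larger part of the shorter interval covered and 106 with lists of the same length.

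Against shared DHS the odds ratio depended on how DHS width was treated. GR peaks lay in 8802 of 48397 shared DHS (18.2%, 17.8 to 18.5), which is more often than in dex-only DHS, with an odds ratio of 0.605 for dex-only against shared (0.573 to 0.639; Fisher p = 1.71e-78, adjusted p = 2.49e-78). Dex-only DHS were narrower, however, with a median of 476 bp against 631 bp. Within 10 strata of width, an alternative added after seeing the data, the odds ratio reversed to 2.13 (1.99 to 2.28; Mantel-Haenszel test, n = 63473 DHS, p = 3.05e-115, adjusted p = 4.88e-115). The strata used width in the dexamethasone list. At matched DHS with a GR peak that width was itself larger than in the vehicle list (medians of 806 and 714 bp). The strata therefore cannot tell more GR at dex-only DHS from a width that goes with GR. The odds ratio without strata stayed below 1 with all intervals reduced to 300 bp (0.656), with lists of the same length (0.753) and with DHS above the median width (0.942, Fisher p = 0.0309). The dex-only share was the higher one in each of the 10 width deciles, for example 33.6% against 17.8% in the seventh decile (median width 665 bp), although the intervals of the widest decile overlap.

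**Figure D2:**
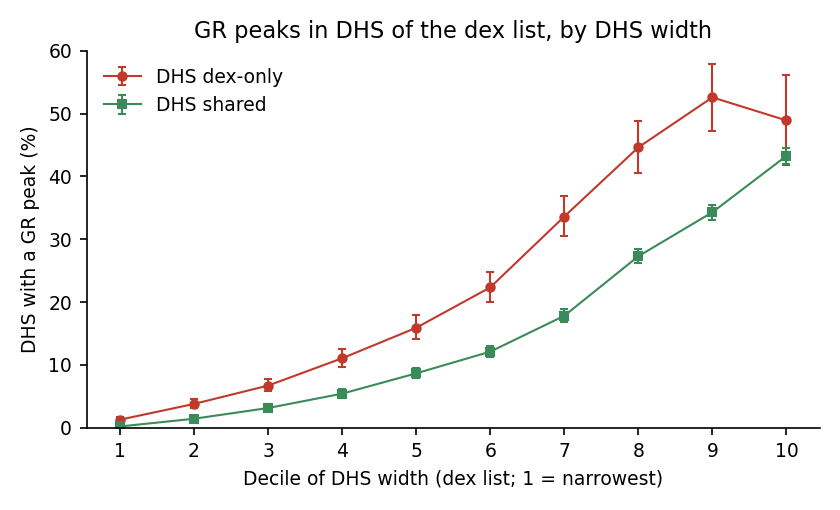
Points give the percent of DHS of the dexamethasone list with a GR peak (y axis) by decile of DHS width (x axis, 1 = narrowest), separately for dex-only and shared DHS, with 95% Wilson intervals. In dex-only DHS the share is 1.30% in the narrowest decile, 52.6% in the ninth and 48.9% in the widest, and in shared DHS it rises from 0.216% to 43.3%.

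Vehicle-only DHS held C/EBPβ less often than shared ones. A vehicle C/EBPβ peak lay in 34.7% of shared DHS of the vehicle list and in 10.9% of vehicle-only DHS (odds ratio 0.231, 0.215 to 0.248; Fisher p below 1e-300). Their median widths were 625 and 453 bp, and with 10 strata of width, added after seeing the data, the odds ratio was 0.409 (0.379 to 0.441). Among dex-only DHS, 29.8% of those with a GR peak and 8.62% of those without one held a dexamethasone C/EBPβ peak. A dexamethasone peak with no vehicle C/EBPβ peak lay in 372 of 1788 dex-only DHS with a GR peak (20.8%, 19.0 to 22.7) and in 386 of 13288 without one (2.90%, 2.63 to 3.20), an odds ratio of 8.78 (7.54 to 10.2; Fisher p = 8.48e-152, adjusted p = 1.51e-151). The DHS with GR were wider (618 against 461 bp), and with width strata the odds ratio was 5.09 (4.27 to 6.07). The comparisons of 0.231 and 8.78 were themselves chosen after seeing the data.

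Within the vehicle state, C/EBPβ was more frequent at DHS with a GR peak. A vehicle C/EBPβ peak lay in 5955 of 8725 vehicle DHS with a GR peak (68.3%, 67.3 to 69.2) and in 11732 of 48069 without one (24.4%, 24.0 to 24.8). With 10 strata of DHS width the odds ratio was 5.23 (4.96 to 5.50; Mantel-Haenszel p below 1e-300), and without strata 6.66 (6.34 to 7.0). DHS with a GR peak were wider, with a median of 719 bp against 576 bp.

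C/EBPβ peaks themselves differed between the lists in the same sense as DHS. The dexamethasone list had 5079 peaks absent from the vehicle list (20%, 19.5 to 20.5), and the vehicle list had 2401 absent from the dexamethasone list (10.6%, 10.2 to 11), with 20313 in both. A GR peak overlapped 1397 dex-only C/EBPβ peaks (27.5%, 26.3 to 28.8) and 37 vehicle-only ones (1.54%, 1.12 to 2.12), an odds ratio of 24.2 (17.4 to 33.7; Fisher p = 7.82e-209, adjusted p = 1.56e-208). This ratio, too, was chosen after seeing the data. Peaks in both lists had GR at 28.9% (28.2 to 29.5), and the odds ratio of dex-only against shared peaks, 0.936 (0.873 to 1.00), did not pass the 0.05 threshold (Fisher p = 0.0584, adjusted p = 0.0584). With other overlap rules it did, with lower odds for dex-only peaks, down to 0.890 (Fisher p = 0.00122).

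**Figure D3:**
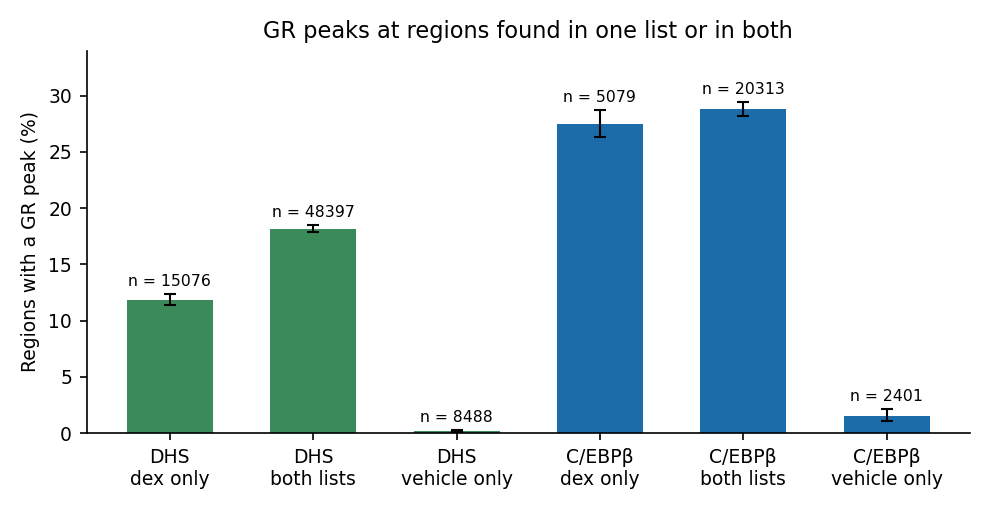
Bars give the percent of DHS (green) and of C/EBPβ peaks (blue) that overlap a GR peak (y axis), for regions in the dexamethasone list only, in both lists and in the vehicle list only, with 95% Wilson intervals and the number of regions. GR peaks lie at 0.153% of vehicle-only DHS and 1.54% of vehicle-only C/EBPβ peaks, against 11.9% and 27.5% of dex-only ones. Most GR peaks overlap a dexamethasone DHS, which vehicle-only DHS by definition do not, so their low share is largely built in.

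Most dex-only C/EBPβ peaks lay in chromatin that was accessible in vehicle livers. A vehicle DHS overlapped 3427 of the 5079 (67.5%, 66.2 to 68.7), a dex-only DHS 777 (15.3%, 14.3 to 16.3), a shared DHS beyond its vehicle interval 120 (2.36%, 1.98 to 2.82), and no DHS 755 (14.9%, 13.9 to 15.9). Of C/EBPβ peaks in both lists, 84.5% lay in vehicle DHS and 10.5% in no DHS. Of vehicle-only C/EBPβ peaks, 68.7% lay in vehicle DHS, close to the share of dex-only ones. Dex-only C/EBPβ peaks in dex-only DHS had a GR peak in 356 of 777 cases (45.8%, 42.3 to 49.3), more often than the 966 of 3427 (28.2%) in vehicle DHS, with an odds ratio of 2.15 (1.84 to 2.53; Fisher p = 1.21e-20, adjusted p = 2.43e-20 within the split). GR-bound dex-only C/EBPβ peaks were almost all in a DHS of the dexamethasone list (98.5%), against 77.9% of the GR-free ones. Of all 11666 GR peaks, 11270 overlapped a dexamethasone DHS, so the 98.5% was near the share for GR peaks in general.

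The intervals carry no signal, so the width of DHS present in both lists was compared in its place, a choice made after seeing the data. DHS with a GR peak were wider after dexamethasone. Among 44381 DHS matched one to one, the 8114 with a GR peak had a median log2 ratio of dexamethasone over vehicle width of 0.12, with median widths of 806 and 714 bp, and 70.8% were wider in the dexamethasone list. The 36267 without GR had a median of -0.02, and 46.7% were wider. The difference of 0.14 (jackknife standard error 0.00326 over chromosomes) was positive on 20 of 20 chromosomes (permutation test over DHS, two-sided, p = 0.00001, the smallest that 100000 permutations can give). GR-bound DHS with C/EBPβ in the dexamethasone list only had a median of 0.30 (870 DHS), those with no C/EBPβ peak 0.20 (1715 DHS), and those with C/EBPβ in both lists 0.08 (5483 DHS). GR-free DHS with C/EBPβ in the vehicle list only had a median of -0.13 (1041 DHS). A wider interval can also take in a C/EBPβ peak more often, and C/EBPβ was not assigned by the part common to both intervals. The order by C/EBPβ may therefore come in part from overlap. Vehicle widths of the GR-bound groups also differed and were not held equal. Their medians were 658 bp with C/EBPβ in the dexamethasone list only, 645 bp with none and 745 bp with C/EBPβ in both lists.

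**Figure D4:**
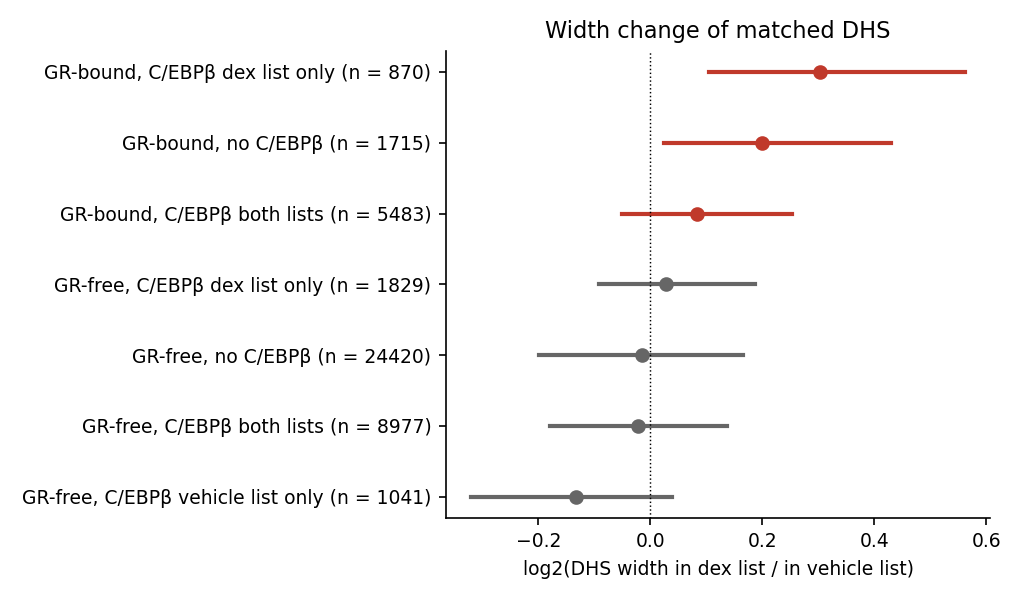
Points give the median and lines the quartile range of log2 DHS width in the dexamethasone list over the vehicle list (x axis), for matched DHS grouped by GR and C/EBPβ peaks (y axis, with the number of DHS). Medians run from 0.30 in GR-bound DHS with C/EBPβ in the dexamethasone list only to -0.13 in GR-free DHS with C/EBPβ in the vehicle list only.

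GR peaks were unevenly spread over the genome. Windows of 100 kb with 5 or more GR peaks (513 of the 5402 windows that held any) contained 28.0% of all GR peaks. The 5 windows with most GR peaks began at 167600000 on chromosome 2 (17 GR peaks), 90400000 on chromosome 6 (16), 46000000 and 48500000 on chromosome 9 (15 and 14) and 32200000 on chromosome 2 (13). In these windows most GR peaks lay outside dex-only DHS, with between 0 and 4 in them. The same held for GR peaks in general, of which 15.6% lay in dex-only DHS. In the order given, these windows held 5, 12, 12, 6 and 8 vehicle C/EBPβ peaks and 13, 19, 13, 11 and 10 dexamethasone ones. The windows with most dex-only DHS were different ones. They began at 14900000 on chromosome 5 (15 dex-only DHS), 25400000 on chromosome 3 (10), 138700000 on chromosome 4 (10), 70700000 on chromosome 14 (10) and 85200000 on chromosome 1 (9). Those on chromosomes 5, 3 and 1 held 0 GR peaks and 0 C/EBPβ peaks, while the chromosome 14 window held 5 GR peaks and 12 dexamethasone C/EBPβ peaks. The named windows on chromosome 6, on chromosome 9 from 46000000 and on chromosome 3 were among the 7 windows with over 22 DHS in a list, which an alternative added after seeing the data left out. The widest dex-only DHS, named by width because the lists have no score, spanned 105579325 to 105587672 on chromosome 12 (8347 bp) and overlapped a GR peak and a dexamethasone C/EBPβ peak. The next widest, 106132196 to 106135739 on chromosome 9 (3543 bp), overlapped a GR peak and no C/EBPβ peak. The other 3 of the 5 widest had no GR peak: 96696191 to 96698918 on chromosome 8 and 7101943 to 7104288 on chromosome 11, each with a dexamethasone C/EBPβ peak, and 65112690 to 65114940 on chromosome 17, without one. None of the 5 widest vehicle-only DHS overlapped a GR peak, among them the widest, 65408059 to 65411760 on chromosome 18 (3701 bp). Genes at these positions were not analysed here, since no mm9 annotation was used.

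Ranked by GR peaks in dexamethasone DHS outside vehicle DHS, an order chosen after seeing the data, the first window began at 28600000 on chromosome 17. Of its 9 GR peaks, 5 lay in dex-only DHS and 3 in shared DHS beyond the vehicle interval. The neighbouring window from 28500000 held 4 and 2 such peaks among its 10. Together these windows had 13 vehicle and 27 dexamethasone DHS, 6 vehicle and 14 dexamethasone C/EBPβ peaks, and 19 GR peaks, of which 15 were outside vehicle DHS.

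**Figure D5:**
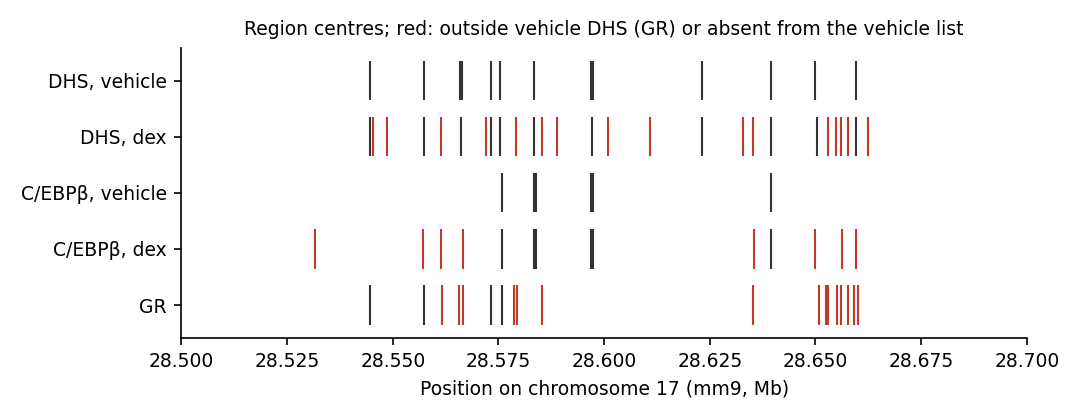
Ticks mark the centres of vehicle DHS, dexamethasone DHS, vehicle C/EBPβ, dexamethasone C/EBPβ and GR intervals (rows) on chromosome 17 from 28.5 to 28.7 Mb (x axis, mm9). Red ticks are dexamethasone DHS (16 of 27) and C/EBPβ peaks (8 of 14) absent from the vehicle list, and GR peaks outside vehicle DHS (15 of 19).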

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

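Of 132 values recomputed under alternatives, 15 equalled the reported value, most because the setting cannot move it (values from the vehicle DHS list alone at equal lengths, C/EBPβ shares set by the merge, observed shares under local placement). Of the other 117, 94 kept their direction and side of the threshold or stayed within their interval. The comparisons against vehicle-only regions, those of C/EBPβ at list-only DHS and the width ratio were chosen after seeing the data. So were the width strata for GR at dex-only DHS, for C/EBPβ at list-only DHS and for C/EBPβ at GR peaks. The set without over-represented DHS widths was also chosen then. The odds of GR at dex-only against shared DHS reversed to 2.13 with width strata. The odds of GR at dex-only against shared C/EBPβ peaks passed the threshold, still below 1, with the larger part of an interval covered (0.890), the centre rule (0.905), the 500-bp rule (0.896) and 300-bp intervals (0.931). In that order, the dex-only share of DHS was 24.5%, 25.2%, 20.7% and 26.7%, and the vehicle-only share 15.6%, 16.2%, 12.9% and 18.2%. With DHS above the median width the shares were 28.8% and 20.2%, and with lists of the same length 19.97% and 18.7%. Without the over-represented widths, chromosome Y and dense windows the dex-only share was 23.4%. With the 500-bp rule, the dex-only and vehicle-only shares of C/EBPβ peaks were 18.5% and 9.94%. The width difference was 0.14 with the 500-bp rule, 0.10 above the median width and 0.13 with equal lengths. Some of these shifts follow from the setting itself, such as the close list-only shares with lists of the same length. The cause of the other shifts was not tested. C/EBPβ lists were not cut by width, which their merging had set, and distances were recomputed only where a setting drops GR or C/EBPβ peaks. No paired analysis was possible because the lists hold no values per replicate, so no replicate was left out either. Depth is unknown, so a region absent from a list is one not called at an unknown depth.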

Other observations

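Of the tests reported here, the one on the width of GR-free dex-only DHS was chosen after the result was seen, as were the comparisons on chromosome X and of DHS width themselves and the ratios for lists of the same length.

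DHS on chromosome X held few GR peaks. A GR peak lay in 96 of 1919 X-linked DHS of the dexamethasone list (5.0%, 4.11 to 6.07), against 17.1% on autosomes, where the 19 chromosomes ranged from 15.4% to 18.7%. C/EBPβ peaks of the dexamethasone list lay in 15.1% of X-linked and 32.4% of autosomal DHS. The window from 137000000 to 137100000 on X alone held 12 of the X-linked GR peaks (11.8%). A single X copy in male animals could lower every signal against a fixed threshold. Among DHS of equal width that explanation required an odds ratio of about 1, as far as width stands for signal. The odds ratio of a GR peak on X was still 0.345 (0.279 to 0.427). In the same strata dexamethasone C/EBPβ peaks were also fewer on X (0.472, 0.413 to 0.539), so the deficit was not particular to GR. A loss of calls on a single X in both ChIP-seq assays therefore stays open. With called C/EBPβ peaks and width held equal the odds ratio of a GR peak was 0.422 (0.338 to 0.527). Fewer called C/EBPβ peaks on X thus did not account for the whole deficit. C/EBPβ was held equal only as a called peak or none, so weaker or uncalled C/EBPβ on X was not held equal and stays open. Part of the GR deficit went with width and C/EBPβ, as the odds ratio without strata was 0.256.

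GR-bound DHS were wider in the dexamethasone list, by 0.14 on the log2 scale relative to GR-free DHS. A wider interval takes in a GR peak more often, but when GR was assigned only by the part common to both intervals the difference was 0.136 (standard error 0.00410). Wide DHS widening with or without GR was also argued against, since within deciles of mean width the difference was 0.150 (standard error 0.00358). Opening of chromatin around GR binding sites was not itself tested and stays open. Width is a stand-in for signal, and the calling method, which can tie interval width to read depth, was not tested.

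The dexamethasone list had 1.78 times as many list-only DHS as the vehicle list, and 88.1% of them had no GR peak. Without GR-bound DHS the ratio was 1.57. An alternative cut both lists to the same length by width, leaving the narrowest DHS out of the dexamethasone list. The ratios were then 1.07 for all and 0.907 for GR-free DHS. Lists of equal length that mostly match one to one must have nearly equal list-only counts (11344 and 10607 here). These ratios therefore do not bear on why the dexamethasone list held more DHS. GR below the level of a called peak is a candidate explanation: GR-free dex-only DHS lay within 10 kb of a GR peak more often than GR-free vehicle-only DHS did (24.0% against 17.2%, odds ratio 1.52, 1.42 to 1.63), although GR-free shared DHS were at 22.9%. Calls near the threshold that a deeper library passes are another, since these DHS had a median width of 461 bp, close to 453 bp in vehicle-only DHS and below 600 bp in shared ones. The dexamethasone list was 1.12 times as long as the vehicle list for both DHS and C/EBPβ, and both explanations remain open.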
